A study of Brassica rapa subsp. pekinensis with 2 samples.

How the data were processed

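Messenger RNA levels were measured by RNA sequencing in 1 library of fertile buds and 1 library of sterile buds of the Chinese cabbage line AB02. Per the labels' protocols, vernalized seeds were grown in a greenhouse, RNA was isolated with Trizol and checked on a Bioanalyzer and an agarose gel, and libraries followed Illumina protocols. TopHat was used, per the submitters' processing notes. Its version, the genome build, the gene annotation and the read counter were not given in the sources used here.

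The authors deposited expression as RPKM, reads normalised to gene length and library total, per the file headers. The table held 51357 features, of which 41019 were genes with Bra identifiers and 10338 were ribosomal RNA features. Gene counts and scalings here used the genes alone. The authors also deposited a comparison of the 2 libraries with log2 fold changes of fertile over sterile, p-values and q-values, per the file headers. That table listed 1012 genes and 1 ribosomal RNA feature, and its highest q-value among the genes was 0.000999. The test behind these values was not given in the sources used here. In the authors' deposited table, the log2 fold changes exceeded the log2 RPKM ratio by 0.239 in each of the 531 genes above 0 in both libraries, so the authors applied a further scaling. The genes of the authors' deposited table are termed called genes here. The authors' other tables were used for names and groups. The first gave Arabidopsis locus codes for 82 called genes, with descriptions for 66 of them. Per the deposited notes, it held genes of unknown function expressed in 1 kind of bud, searched with BLASTN. The second gave KEGG pathways with p-values and corrected p-values by the authors, and the locus codes of 143 called genes.

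Names were therefore paired with 225 called genes, and 787 called genes and the genes outside the authors' deposited table carried an identifier alone. The RefSeq gene table of assembly CAAS_Brap_v3.01 was searched for the Bra identifiers and added no name used here. Genome coordinates were not used here.

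Read depth was recovered from the RPKM values. For the 475 called genes at 0 in the sterile library and the 6 at 0 in the fertile library, the fold change in the authors' deposited table was proportional to the number of reads, which gave whole reads within 9.2e-11 of a whole number against a tolerance of 0.0001. With gene lengths taken as multiples of 3 bp, as coding lengths are, the library totals behind the RPKM values came to 1803154 reads in the fertile and 1567647 reads in the sterile library. The totals rest on that length step and would be 3 times larger with steps of 1 bp, and the read numbers of these 481 genes do not depend on it. For the other genes, the smallest whole reads that give both RPKM values were used, which is a minimum because the true reads can be a multiple. In 4000 simulated genes with known reads this recovered the exact reads of 85.3% of genes above 0 in both libraries and of 65.2% of genes at 0 in 1 library, and it exceeded the true reads in 0%. In the 475 called genes at 0 in the sterile library the minimum equalled the exact reads in 62.3%. The recovered minimum reads made up 88% of the fertile and 88.8% of the sterile total.

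Genes with RPKM of at least 1 in at least 1 library were kept. A gene was counted as lower or higher in sterile buds when log2(RPKM + 1) differed by at least 1 between the libraries. This is a rule of size and not a test, and log2(RPKM + 1) understates the difference of genes with low values. Differences are given as sterile minus fertile. Since each group had 1 library, no p-value across genes was computed, and a test on the reads would compare these libraries and not the conditions. Ratios of single genes are given with a 95% Clopper-Pearson counting interval of the reads. For a gene with 0 reads in a library, the fold is a bound computed against 3 reads in that library. Bounds leave out the counting error of the other library, so the lower end of the 95% counting interval lies below them. For Bra005946, for example, the bound was 713 and the lower end 580. Sequencing reads are not independent molecules, so intervals cover counting error only and bounds only a part of it. Where the true reads are a multiple of the minimum, the interval given is wider than that of the true reads would be.

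The rule was tested on simulated libraries of 30651 genes at these depths, with 50 genes per fold size. Genes differing 2-fold passed the size rule in 48% of cases, 4-fold in 96%, 8-fold in 100% and 16-fold in 100%. With a counting interval that also excluded equality the shares were 42%, 80%, 96% and 100%. Unchanged genes passed the size rule in 11.6% of cases, and in 1.33% with the interval.

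Before the data were examined, 28 gene lists were fixed by Arabidopsis code, symbol or description keyword, covering anther and pollen stages, other cell types of a bud, and gene families. List medians were set against 10000 random lists of the same size matched on mean level in 20 bins, where at least 3 members had a name. Genes were named by a rule fixed at the same time. It took the 10 named genes with the largest difference in each direction, up to 4 members of each list, the 5 named genes with the largest fold change in each table of the authors, the most abundant genes, and at most 2 identifiers without a name in each direction. Other genes named as members of the authors' pathways were chosen after their values were seen.

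Alternatives fixed at the same time were pseudocounts of 0.1, 0.5 and 5, no filter or RPKM of at least 5, a difference of at least 2, 3 other scalings of the sterile library, leaving the 100 most abundant genes out of the scale, 5 bins, and list means. The trimmed mean of log ratios removed 30% of the log ratios and 5% of the mean levels at each end. Counting intervals as a criterion, thinning of the fertile reads, and random lists drawn from the called genes, matched in 5 bins, were added after seeing the data. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.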

Results

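Flower buds of male fertile and male sterile plants were compared in AB02, a male sterile AB line of Chinese cabbage (Brassica rapa subsp. pekinensis). An AB line is maintained as a population that segregates into fertile and sterile plants. In this line the sterility is inherited through multiple alleles of a nuclear locus. RNA was sequenced from 1 library of fertile buds and 1 library of sterile buds, so no difference reported here has a replicate check. With gene lengths taken in steps of 3 bp, as coding lengths, the RPKM values corresponded to totals of 1803154 reads in the fertile and 1567647 reads in the sterile library. With steps of 1 bp the totals would be 3 times larger, at a median length of 311 bp instead of 933 bp over the 481 genes with exact reads. At the former totals 1 read in a gene of 1 kb was worth 0.555 RPKM in the fertile and 0.638 RPKM in the sterile library, and 3 reads were worth 1.66 and 1.91 RPKM. Of 41019 genes, 29071 (70.9%) were above 0 in fertile buds and 27279 (66.5%) in sterile buds. The median RPKM over the genes was 3.44 in fertile and 3.07 in sterile buds. The 10 most abundant genes held 5.82% of the summed RPKM in fertile and 7.15% in sterile buds.

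The comparison asked which mRNAs differ between sterile and fertile buds. Transcripts for several pectin-degrading enzymes, several proteins of the DUF1216 family and an oleosin were abundant in fertile buds and had 0 reads in sterile buds. Transcripts for 3 peroxidases and a serine acetyltransferase were higher in sterile buds, while 3 copies of another peroxidase gene were lower. Of the 4 named cytochrome P450 genes, 2 were higher and 2 were lower. Among the 27940 genes kept, 4042 were lower and 3224 were higher in sterile buds by at least 1 on the log2(RPKM + 1) scale, so 55.6% of these were lower. With the sterile library rescaled by the median ratio 65.8% were lower, and with the trimmed mean of log ratios 67.3% were lower. The balance was more uneven among large differences. By at least 2 on the same scale, 1888 genes were lower and 556 were higher. The 95% counting interval of the ratio excluded any difference below 2-fold for 1269 lower and 267 higher genes. In the fertile library alone, 635 genes reached RPKM of at least 10 while at 0 in the sterile library, and in the reverse direction 47 genes did. Most genes lay slightly higher in RPKM in the sterile library, with a median difference of 0.17 over the kept genes. Relative to that median, each difference given here is lower by the same amount. RPKM is relative to the library total, so this shared shift need not be a change in the mRNA of most genes. The ribosomal RNA feature rRNA06148 stood at 6696 RPKM in fertile and 818.8 RPKM in sterile buds.

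**Figure D1:**
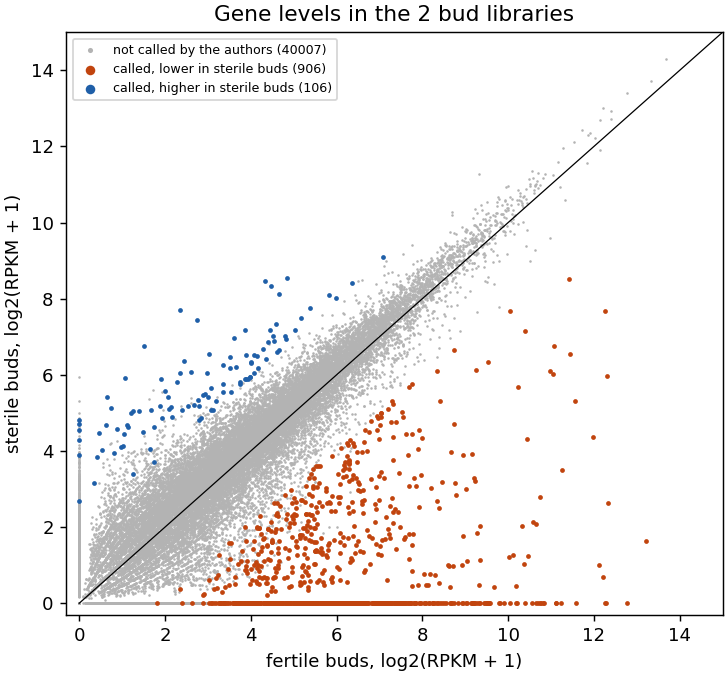
Level of each of the 41019 genes in sterile buds against fertile buds, both as log2(RPKM + 1), 1 library per group, with the line of equal levels. Orange and blue points are the 906 and 106 genes that the authors' deposited table lists as higher in fertile and in sterile buds, and 475 of the orange points lie at 0 in sterile buds.

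The authors' deposited table listed 906 genes as higher in fertile buds and 106 as higher in sterile buds. The size rule took in 1012 of the 1012 genes in the same direction, which follows from their large folds in the same RPKM values. The scalings tried moved the log2 values of sterile buds by between -0.23 and 0, too little to turn the direction of a called gene. Called genes that were higher in fertile buds held 16.7% of the summed RPKM in fertile buds and 0.319% in sterile buds. Those higher in sterile buds held 0.101% in fertile and 0.695% in sterile buds. There were 475 called genes with 0 reads in sterile buds, and these had between 27 and 7817 reads in fertile buds. In the other direction 6 called genes had 0 reads in fertile buds. A further 6254 genes passed the size rule without being listed in the authors' deposited table. The genes listed there had q-values of at most 0.001 and, where above 0 in both libraries, RPKM ratios of at least 4.03, and 2446 of the 6254 genes were above 0 in both libraries with ratios under 4.03.

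The genes with the largest differences had 0 reads in sterile buds. Bra028691, a gene with no name here, had 6991 RPKM in fertile buds and was at least 1640-fold lower in sterile buds. Like the other folds given as at least, this is set against 3 reads, and the lower end of its counting interval was 1340. Bra009255, also without a name, had 4995 RPKM and was at least 853-fold lower. Among genes with an Arabidopsis counterpart, Bra005946 (AT5G07572) had 4894 RPKM in fertile buds and was at least 713-fold lower in sterile buds. Bra028692 (AT5G07571), which carries an oleosin domain, had 2401 RPKM and was at least 373-fold lower. Oleosins coat lipid bodies in pollen, tapetum and seeds. Bra025352 (AT3G28750) had the most reads of these genes, 7817, and at 3049 RPKM it was at least 2270-fold lower in sterile buds. Its log2 fold change of fertile over sterile was 13.2 in the authors' deposited table. Bra025386 (AT3G28810) had 1672 RPKM and was at least 477-fold lower, and Bra032390 (AT3G28980) had 589 RPKM and was at least 436-fold lower. Like Bra025352, both encode proteins with the DUF1216 domain, of unknown function. The deposited descriptions named this domain in 8 genes, which ranged from 182 to 3049 RPKM in fertile buds. Another 4 called genes with the same Arabidopsis codes ranged from 12.4 to 112 RPKM. Bra010803 (AT1G30020) was at least 248-fold lower, and Bra008396 (AT1G51250) at least 166-fold lower. Bra022674 (AT5G53820) encodes a late embryogenesis abundant protein, a family linked to desiccation, and was at least 95.6-fold lower from 897 RPKM. Bra007349 (AT2G41905), whose closest match is an arabinogalactan protein of the cell wall, was at least 72.4-fold lower from 745 RPKM. Bra023621 (PC1), a calcium-binding protein, was at least 77.4-fold lower from 617 RPKM.

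The authors' deposited table of genes expressed in 1 kind of bud held 82 genes, chosen by the authors for 0 reads in the other kind, and the 82 were at 0 in sterile buds. Descriptions were filled in for 66 of them and empty for 16. Of the 66, 44 mentioned pollen, the male gametophyte or sperm cells, 38 mentioned the mature pollen stage, and 22 mentioned none of the former. A location in the endomembrane system was given for 28, and 2 mentioned formation of the pollen exine, the outer pollen wall. How often such words occur in descriptions of other genes was not examined here, so these numbers do not set the 82 genes apart. The 82 genes held 2.01% of the summed RPKM in fertile buds, with a median of 93.2 RPKM.

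**Figure D2:**
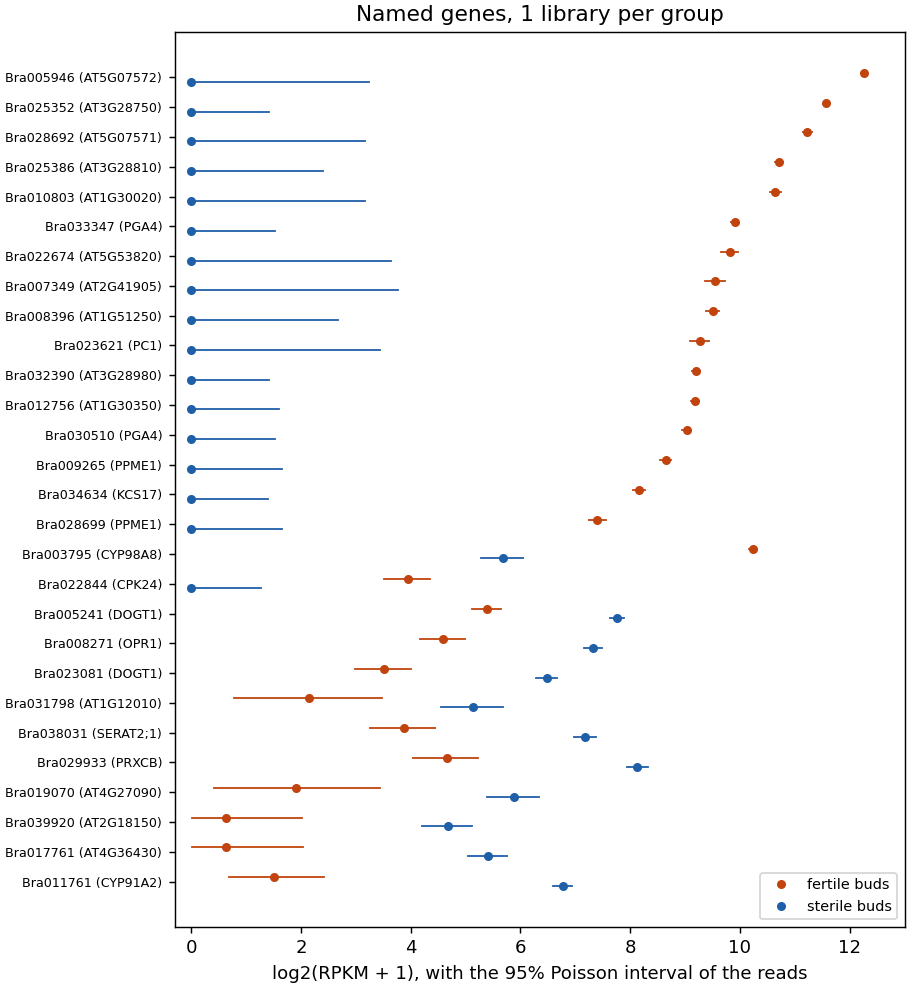
Levels of the named genes in fertile buds (orange) and sterile buds (blue) as log2(RPKM + 1), 1 library per group, with 95% Poisson intervals of the reads that cover counting error only. PGA4, PPME1 and KCS17 genes lie at 0 in sterile buds, whereas CYP91A2, PRXCB and SERAT2;1 lie higher there.

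Pectin-degrading enzymes formed the pathway with the smallest p-value in the authors' enrichment. Its 20 genes, listed under pentose and glucuronate interconversions, were all lower in sterile buds, and 17 of them had 0 reads there. In the authors' deposited table this pathway had 11 of 62 Arabidopsis genes, with a p-value of 5.69e-06 and a corrected p-value of 0.000678. The 4 copies of PGA4, a polygalacturonase, were led by Bra033347 at 959 RPKM in fertile buds, at least 633-fold lower in sterile buds, and by Bra030510, at least 345-fold lower. Bra012756 (AT1G30350), a pectin lyase family gene, had 579 RPKM and was at least 354-fold lower. The pectin methylesterase gene PPME1, which acts in pollen tube walls, was at least 230-fold lower in Bra009265 and at least 95.9-fold lower in Bra028699. The pectate lyase gene AT59 had a minimum of 146 reads in fertile and 1 read in sterile buds for Bra016700. Its ratio was 127, with a counting interval from 22.4 to 5050. The other AT59 copy, Bra026221, was at least 18-fold lower. A further member, Bra024619 (ALDH2B7), is an aldehyde dehydrogenase and not a pectin enzyme, and it was 15.9-fold lower (interval 8.94 to 31.3). The median difference of the 20 genes was -5.59 on the log2(RPKM + 1) scale, and -5.71 as a log2 ratio with genes at 0 set to their bound. The authors' deposited table held 76 pathways, and the next smallest corrected p-value was 0.784.

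**Figure D3:**
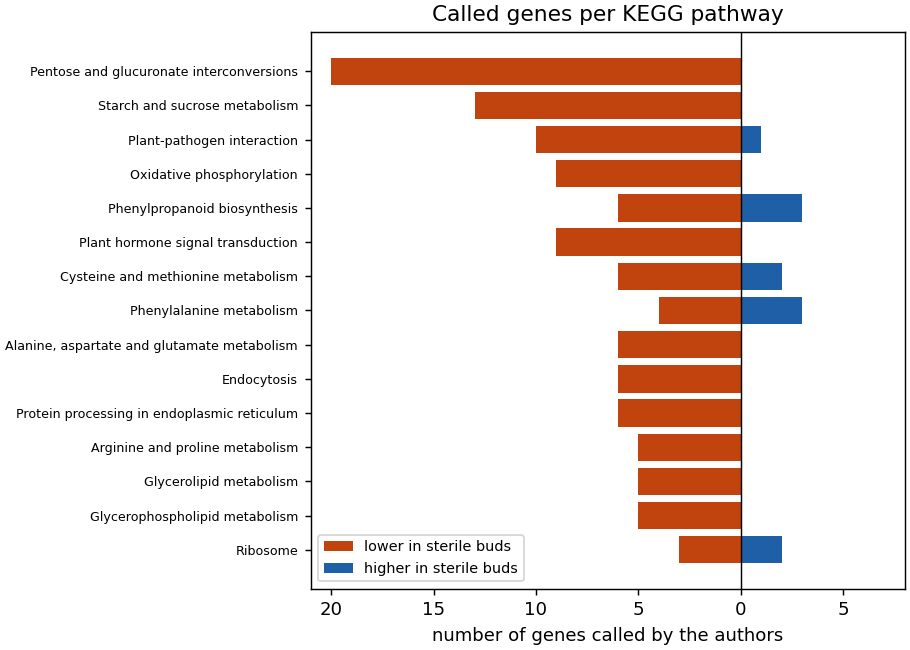
Number of called genes in each KEGG pathway of the authors' deposited table with at least 5 genes, lower (orange, left) or higher (blue, right) in sterile buds; the 2 collective terms for metabolism are left out. Pentose and glucuronate interconversions held 20 genes, all lower, and phenylpropanoid biosynthesis held 6 lower and 3 higher genes.

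Other pathways did not pass the authors' correction but held genes with large differences. Of the 1012 called genes 89.5% were lower in sterile buds, so counts of lower genes do not set these pathways apart. Starch and sucrose metabolism had 13 genes, all lower in sterile buds, and 9 of them were pectin enzymes of the former pathway (corrected p-value of 0.805 in the authors' deposited table). Oxidative phosphorylation had 9 genes, all lower, with 7 at 0 reads in sterile buds (corrected p-value of 1 in the authors' deposited table). These were mostly proton pumps and not respiratory chain subunits. Bra035163 (HA9), a plasma membrane proton pump, was at least 61.1-fold lower, Bra013168 (HA6) at least 21.4-fold lower, and Bra013935 (VATG3), a subunit of the vacuolar pump, at least 14.2-fold lower. The 11 genes listed under plant-pathogen interaction included calcium-binding proteins such as PC1 and the calcium-dependent kinase CPK24, and 10 were lower (corrected p-value of 0.805 in the authors' deposited table). In this group Bra022844 (CPK24) had 43 reads in fertile buds and was at least 12.5-fold lower. Bra012889 (CML41), a calmodulin-like protein, was 4.13-fold higher in sterile buds (interval 3.15 to 5.48). For fatty acid elongation, 4 of 4 genes were lower (corrected p-value of 0.805 in the authors' deposited table). Its Bra034634 (KCS17), a ketoacyl-CoA synthase, was at least 212-fold lower from 285 RPKM.

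In the lists fixed beforehand, the late pollen and pollen tube genes with a name were lower in sterile buds. This list had 38 entries and 4 named genes, the PPME1 and AT59 copies, and each was lower. Their median difference was -6.38 on the log2(RPKM + 1) scale, at percentile 0 among random lists of matched level, whose median was 0.16. That percentile carries no weight, because a list member had a name only if the authors had called it. Copies of the same gene are also not separate draws. With genes at 0 set to their bound the median log2 ratio was -6.79. Among random lists drawn from the called genes, whose median was -4.92, the percentile was 11.8, so the list did not stand apart from other called genes. Cytochrome P450 genes went in both directions. Bra003795 (CYP98A8), which hydroxylates phenolamides of the pollen coat, was 23.9-fold lower in sterile buds, from 1200 to 50.3 RPKM (interval 18.3 to 31.7). Bra006830 (CYP81F2), an enzyme of indole glucosinolate synthesis, was 5.59-fold lower (interval 2.5 to 14.7). Bra011761 (CYP91A2) was 58.4-fold higher in sterile buds (interval 24.7 to 182) and Bra036345 (CYP71B22) 4.43-fold higher (interval 2.68 to 7.65). Their median difference of -0.07 lay at percentile 16.6 among random lists, and its sign turned with the pseudocount. Among random lists drawn from the called genes, whose median was -4.59, the percentile was 97.7. In 4 lists 1 gene had a name, namely CYP98A8 for sporopollenin and exine, Bra007349 for arabinogalactan proteins, Bra028692 for lipid transfer proteins and oleosins, and CPK24 for receptor-like and calcium-dependent kinases.

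The other 22 lists had 0 members by the matching rule. Lists of single genes were matched on the Arabidopsis codes, which were paired here with 225 called genes alone. Gene families were matched by keyword on symbols and descriptions, and the pathway genes carried codes and symbols without a description. They were early anther regulators, pollen coat proteins, callose wall, meiosis, anther jasmonate, floral organ identity, pistil and ovule, housekeeping and photosynthesis genes. They also included pectin modification, callose synthases, sugar transport, flavonoid enzymes, ribosomal proteins, histones, heat shock proteins, 3 transcription factor families, exocyst and actin, cell death proteases, and a jasmonate keyword list. Some genes named elsewhere, such as PGA4, belong to these families but were not matched by keyword. Medians of the 22 lists, including the markers of other bud cell types, were not analysed here.

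Of the 225 named genes, 14 were higher in sterile buds, all of them pathway genes. The 82 genes chosen by the authors for 0 reads in 1 kind of bud were at 0 there, so they could not be higher. Of the 143 pathway genes 90.2% were lower, near the 89.5% of the 1012 called genes. Among the 14, the largest difference on the log2(RPKM + 1) scale was that of CYP91A2, at 1.85 RPKM in fertile and 108 RPKM in sterile buds. By ratio the largest was that of a peroxidase gene, and 3 peroxidase genes of the phenylpropanoid pathway were higher. Bra017761 (AT4G36430) had a minimum of 1 read in fertile and 65 reads in sterile buds, a ratio of 74.8 (interval 13 to 3000). Bra039920 (AT2G18150) had a minimum of 1 and 39 reads, a ratio of 44.9 (interval 7.59 to 1820). Bra029933 (PRXCB) was 11.5-fold higher (interval 7.48 to 18.5), at 280 RPKM in sterile buds. Other peroxidase genes of the same pathway were lower in sterile buds. Of the 3 copies of AT5G47000, Bra022090 was at least 51.3-fold lower, Bra017514 at least 19.7-fold lower and Bra024972 34.2-fold lower (interval 11.4 to 168). Phenylpropanoid biosynthesis held 6 lower and 3 higher genes, with a corrected p-value of 0.805 in the authors' deposited table.

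Bra019070 (AT4G27090), a ribosomal protein gene, was 21.3-fold higher in sterile buds (interval 5.49 to 182). Bra038031 (SERAT2;1), a serine acetyltransferase of cysteine synthesis, was 10.5-fold higher (interval 6.75 to 17.1). Bra031798 (AT1G12010), an oxygenase of the ethylene-forming type, was 9.97-fold higher from a minimum of 3 reads in fertile buds (interval 3.06 to 51.5). Both copies of the glucosyltransferase gene DOGT1, which acts on brassinosteroids and zeatin, were higher, Bra023081 by 8.46-fold (interval 5.69 to 13) and Bra005241 by 5.3-fold (interval 4.31 to 6.58). Bra008271 (OPR1), an oxophytodienoate reductase, was 6.88-fold higher (interval 5.04 to 9.58). Among genes without a name, Bra019035 had 0 reads in fertile and a minimum of 10 reads in sterile buds. It was 3.83-fold higher against 3 reads, with 2.58 as the lower end of its counting interval. The authors' deposited table did not list it. The most abundant gene of both libraries, Bra029765, had 13040 RPKM in fertile and 20130 RPKM in sterile buds, a ratio of 1.54 (interval 1.49 to 1.6). Its size depended on the scaling. The difference on the log2(RPKM + 1) scale was 0.63, against 0.42 with the median ratio and 0.39 with the trimmed mean, both outside the counting interval.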

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

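The neighbouring identifiers and their directions were tested only after the pattern had been seen, as were the thinning of reads and the counting intervals behind the first pattern. A signal in data outside the gene comparison was found in a ribosomal RNA feature. The feature rRNA06148 had 6696.4 RPKM in fertile and 818.8 RPKM in sterile buds, a ratio of 8.178 of fertile over sterile, and 3 other ribosomal RNA features were above 0 in at least 1 library, at a minimum of 2 or fewer reads in fertile and 3 or fewer in sterile buds.

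Large differences were mostly lower levels in sterile buds, with 82.6% of the genes whose counting interval excluded a difference below 2-fold being lower there. That share was 82.6% or more under each planned scaling, which cannot decide whether the scaling of the libraries was the cause. The planned scalings moved the log2 values of sterile buds by between -0.23 and 0, and such moves cannot lower the share. The greater depth of the fertile library is argued against, since the share was 83.9% after the fertile reads were thinned to the sterile depth. The share was 85% with the 100 most abundant genes of each library left out of the scale and the count. This omission could hardly lower the share, because it took out few of the 1269 lower genes and moved the log2 values of sterile buds by -0.07. It shows only that the excess of lower genes was not confined to the most abundant genes. Fertility of the buds, a difference between the sampled plants and a difference in bud stage stay open, because with 1 library per group they cannot be separated.

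The size rule passed 7266 genes, against 1012 called by the authors. Libraries drawn with no true difference at these depths gave a mean of 3164 such genes over 100 draws, or 43.5% of the observed number, with a range from 3072 to 3262. No draw reached the observed number, and the share lay under the bound set beforehand for arguing against counting error alone. That bound was judged wrong for this design after the value was seen, because the draws hold no variation between samples and 2 separate bud samples would be expected to exceed them with or without a difference in fertility. With 1 library per group, counting error, variation between samples and fertility cannot be told apart as sources of these genes.

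Called genes lay next to each other by identifier number more often than random genes of the same level. There were 69 pairs of called genes with consecutive numbers, against a mean of 27 and a highest count of 45 in 1000 random gene sets matched on level, and the 2 longest runs held 4 genes each. In 62 of the 69 pairs both genes went in the same direction, against a mean of 56 and a range from 45 to 66 when the directions were shuffled 1000 times among the called genes. Copies of the same Arabidopsis gene side by side are a candidate explanation that stays open, since 27.3% of the 11 pairs with codes for both genes shared the code (95% Clopper-Pearson interval 6.02% to 61%). Reads shared between similar neighbouring genes could also contribute, and this was not tested.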

How the results depend on the processing

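Using counting intervals as a criterion, thinning, and random lists drawn from called genes were chosen after seeing the data. Lower genes outnumbered higher genes in sterile buds under each setting tried. The counts moved most with a pseudocount of 5 (1935 lower and 987 higher), RPKM of at least 5 (2426 and 2011), a difference of at least 2 (1888 and 556), counting intervals that exclude equality (2130 and 1514), and counting intervals that exclude differences below 2-fold (1269 and 267). Each of these keeps fewer genes with few reads or small differences by construction. Under the other settings the counts stayed within 1.5 times those reported. The late pollen median was -9.34 with a pseudocount of 0.1, -7.17 with 0.5 and -4.33 with 5, as genes at 0 depend on the pseudocount. The cytochrome P450 median turned to 0.08 with a pseudocount of 5 and the list mean was 0.14, since 2 members were lower and 2 higher. The size rule took in between 987 and 1012 of the called genes under the pseudocounts, filters, scalings and the difference of at least 2, as their large folds make it do. The filters left the differences of the 32 named genes in place by construction, as did the scalings for genes at 0 in sterile buds. The equal RPKM sum left the 32 differences in place because the 2 sums were nearly equal, with a factor of 1.001. Of the 130 values that a setting shifted by at least 0.02, 16 left their counting interval, 13 with a pseudocount of 5 and 3 for Bra029765 under scalings. No paired analysis was possible because each group had 1 library. In simulated genes 2-fold differences passed the size rule in 48% of cases, and in 42% with a counting interval. The limit of the size rule lies near 2-fold, so many differences of that size did not pass it.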

Other observations

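Further called genes are given by the authors' pathways, whose corrected p-values lay between 0.784 and 1 in the authors' deposited table. These genes and the shuffling of directions were chosen after their values were seen. Since 90.2% of the pathway genes were lower in sterile buds, the counts do not set these groups apart. Under plant hormone signal transduction, 9 of 9 genes were lower. They included Bra023405 (AT5G13380), a GH3 family gene, with a minimum of 422 reads in fertile and 1 read in sterile buds. Its ratio was 367 (interval 65.5 to 14500), and the interval is too wide if the true reads are a multiple of the minimum. Bra035803 (AT3G20220), a SAUR family gene, was at least 30.1-fold lower, and the 2 copies of JAR1, which conjugates jasmonate, were 5.03-fold (interval 2.83 to 9.61) and 5.74-fold lower (interval 2.93 to 12.5). Under protein processing in the endoplasmic reticulum, 6 of 6 genes were lower, and 4 of these were heat shock genes. The ATHSP22.0 copies Bra000703 and Bra027999 were 40.2-fold (interval 15.4 to 149) and 30.9-fold lower (interval 11.8 to 115). The Hsp70b copies Bra026084 and Bra016644 were 6.4-fold (interval 3.4 to 13.3) and 6.31-fold lower (interval 4.99 to 8.08).

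Cysteine and methionine metabolism held 6 lower and 2 higher genes. Bra014984 (SAHH2), an adenosylhomocysteine hydrolase, was 30.7-fold lower (interval 19 to 53.1), and Bra017219 (MAT3), a methionine adenosyltransferase, 4.28-fold lower (interval 3.65 to 5.05). Bra006334 (SAMDC), of polyamine synthesis, had a minimum of 214 reads in fertile and 2 reads in sterile buds, a ratio of 93 (interval 25.4 to 773). Amino acid genes included Bra018160 (ASN1), an asparagine synthetase, 16.5-fold lower (interval 10.5 to 27.4). They also included Bra036428 (GDH3), a glutamate dehydrogenase, with a ratio of 130 from a minimum of 149 reads against 1 (interval 22.9 to 5150). In terpenoid backbone synthesis, Bra039216 (GGPS2), a geranylgeranyl diphosphate synthase, was 68.1-fold lower from 593 RPKM (interval 40.4 to 125).

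Called copies of the same Arabidopsis gene had the same direction. Among the pathway genes, 23 codes had at least 2 called genes, and in 0 of the 23 did the copies go in opposite directions. With directions shuffled 1000 times among the pathway genes, a mean of 4.55 codes and between 0 and 10 had copies in opposite directions. In 1 of the 23 codes, DOGT1, the copies were higher in sterile buds. Copies that the authors did not call carried no code here, so this holds for called copies alone. Reads shared between similar copies could also contribute to a shared direction, and this was not tested.

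The median log2 ratio of sterile over fertile was 0.23 over the 15905 genes with RPKM of at least 5 in both libraries and 0.25 over the 1870 genes with RPKM of at least 100 in both. Called genes higher in fertile buds held 16.7% of the summed RPKM in fertile and 0.319% in sterile buds. With nearly equal RPKM sums, this leaves a larger share for other genes in sterile buds. The shift therefore need not be a change in their mRNA.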
